A study of Mus musculus with 3 samples.

How the data were processed

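The samples were 3 libraries of total RNA from splenic T cells of B6CASTF1/J mice, with 3 tables per library used here, and all 3 fall into 1 group by their labels. Per the labels, the protocol was a directional RNA library kit with an ERCC spike-in mix, and the replicate numbers are those of the labels. The gene table and the first transcript table hold estimated counts, TPM and FPKM per the file headers. The README deposited with each sample states transcriptome alignments to mm10 with GENCODE annotation M21 for both, and the aligner and quantifier are not given in the sources used here. The second transcript table holds estimated counts and TPM, deposited by the authors, made from the reads against an index of the same annotation per its README, with its tool likewise not given in the sources used here. In the text it is the second quantification, summed per gene. Its deposited lengths and effective lengths gave the mean fragment length, and the deposited posterior SD of the count in the first tables served as a measure of reads that several genes share. Reads were assigned to one reference genome in the deposited tables, and alleles of the 2 parental strains were not analysed here.

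The gene table had 81881 entries per library: 55536 genes, all matched by identifier to the annotation, 96 spike-ins, 1 phiX174 control sequence and 26248 entries named by a number only, which held a mean of 5.67 estimated counts per library and were left out of all tests and library sizes. Spike-ins and phiX174 were left out of the gene tests too. The transcript tables had 168207 and 141864 entries. Estimated counts were 16.93, 15.04 and 16.25 M in replicates 1, 2 and 3 of the gene table and 18.19, 16.43 and 17.57 M in the second quantification. A gene with an observed count of 0 can have a true mean of up to 3 counts, which is 1.77e-05%, 2.00e-05% and 1.85e-05% of the counts of the 3 libraries. PCR copies are not independent molecules, so such floors cover counting error only. Coordinates are 1-based on mm10, from the annotation.

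Before the data were examined, 44 gene lists, the tests, the alternatives and the rule for genes to be named were fixed, while 5 alternatives and the tests of explanations were added later. Of the listed symbols, 9 had no match and were left out. Named genes are up to 5 highest and 2 lowest of each list described, a fixed set of T-cell genes with Xist, the 20 genes with the highest TPM, the 15 most variable genes and up to 5 variable members per list, and the 5 genes with the largest ratio between the quantifications in each direction. Others are named with the remark that they were chosen after their values were seen. The level of a list is the median of log2(TPM + 1) over its genes in a library. Differences of levels were tested over the 3 libraries by exact two-sided sign-flip permutation, which cannot go below p = 0.25 with 3 libraries, with Benjamini-Hochberg adjustment over the 4 tests. Gene detection used a minimum of 1 TPM in all 3 libraries.

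Genes that varied between libraries were sought in edgeR with an intercept-only model, since 1 group has no contrast. Estimated counts were rounded to whole numbers, filtered with filterByExpr and scaled with TMM. The residual quasi-likelihood dispersion of each gene was set against the abundance trend of a robust fit by an F test, adjusted by Benjamini-Hochberg at 0.05 over all genes tested. Tested on simulated data for the spread between the 3 libraries (13280 genes), it recovered 95% of genes changed 2-fold and 100% of genes changed 4-fold in 1 library, all with a mean count of at least 50, with 3 false among 198 calls. All simulated genes had the same dispersion and no shared reads. The rate of false calls in the real libraries is therefore not known from this simulation. Whole-list shifts were the mean over genes of log2(TPM + 1) minus the gene's mean over libraries, with the range over libraries ranked among 10000 random lists from 20 bins of mean expression. Tested on simulated data (21936 genes), 10 of 10 lists changed 1.5-fold and 0 of 10 unchanged lists exceeded the 95th percentile. Genes were again simulated independently at the same dispersion. Pairs of libraries were compared by chi-square over genes with 20 or more summed counts. With 3 libraries no test for outlying samples was run, and with 1 group no split of the samples was tested.

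Alternatives were the second quantification, FPKM, posterior mean TPM and TMM-scaled counts (CPM) in place of TPM, a pseudocount of 0.1, filters on low values, other detection thresholds, DESeq2 size factors, DESeq2's marking of genes with outlying dispersion, no filter or a mean count of 100, a non-robust fit, and each replicate left out. With 3 libraries, a gene called because 1 of them stands apart loses its call when that library is left out. For such genes that loss was set in advance. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.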

Results

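Total RNA was sequenced from mouse T cells of the spleen, labelled female and 66 days of age. The strain, B6CASTF1/J, is the first-generation cross of a C57BL/6 mother and a CAST/EiJ father. The 3 libraries form 1 group and are named replicates 1, 2 and 3, each made from 300 ng of RNA with a spike-in mix of synthetic transcripts. They held 16.93, 15.04 and 16.25 M estimated counts, so that 1 TPM (abundance scaled by effective length and depth) of a transcript of effective length 1 kb stood for 17.03, 15.41 and 17.03 reads. The labels list 3 biosample records under 1 donor record, and p-values and SDs therefore measure only the spread between these samples, which may be technical. With 1 group, the comparisons are between groups of genes within each library, and between the libraries. All levels are means ± SD over the libraries (n = 3).

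Transcripts of the T-cell receptor complex were abundant in every library. All 21 genes of the T-cell core list exceeded 10 TPM. Its highest members were Trbc2 and Trbc1, the constant regions of the receptor beta chain, at 649.6 ± 43.3 and 423 ± 30.3 TPM, and Trac, the alpha constant region, at 492 ± 16.4 TPM. Lck, the kinase that starts receptor signalling, reached 321 ± 10.2 TPM and the CD3 chain gene Cd3e 319 ± 10.2 TPM, while Themis and Ubash3a were lowest at 69.0 ± 1.02 and 34.6 ± 1.92 TPM. All 22 genes of the receptor signalling list also lay above 10 TPM, from Ptprc (CD45, 541 ± 17.1 TPM) and Dgka (277 TPM) down to Nfatc2 (31.4 TPM) and Bcl10 (23.7 TPM). Of 22 T-cell transcription factors, 21 did, led by Tcf7 (389 ± 13.5), Klf2 (354 ± 23.5), Satb1 (329 ± 17.5) and Ets1 (283 ± 4.75), and the lowest was Id3 at 9.50 ± 0.849 TPM.

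Genes of other cell types lay far lower. The question of these comparisons was how far the T-cell label holds against the other cells of the spleen. The median level of the T-cell core list on the log2(TPM + 1) scale was 7.19 ± 0.05, against 1.33 ± 0.38 for 17 B-cell genes and 1.81 ± 0.30 for 18 genes of monocytes and macrophages. The difference from the B-cell list was 5.86 ± 0.42, or 58.1-fold, and from the monocyte and macrophage list 5.38 ± 0.26, or 41.8-fold. These folds are of TPM + 1, and the added 1 lowers them. Without it, the median over genes of mean TPM was 143.5 for the T-cell core, 1.46 for the B-cell and 2.66 for the monocyte and macrophage list. Each difference was positive in 3 of 3 libraries and many times its SD. The exact two-sided sign-flip test gave p = 0.25 for each, the smallest value that 3 libraries allow, and 0.25 after adjustment over the 4 such tests.

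Within the B-cell list, Ighm, the constant region of the immunoglobulin mu chain (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730), stood apart at 139.8 ± 11.9 TPM. The next members were Ighd at 4.06 ± 1.66, Cd79b at 3.79 ± 0.208, Cd22 at 3.44 ± 0.833 and Cd79a at 2.49 ± 1.13 TPM, and Fcer2a was lowest at 0.567 ± 0.368 TPM. Plasma-cell genes included Xbp1 (32.0 ± 0.865 TPM) and Irf4 (6.69 ± 2.47 TPM), which many cells use, while Jchain reached 1.35 ± 0.682 TPM and Tnfrsf17 was at 0. In the monocyte and macrophage list Ly6c2 (42.6 ± 9.13 TPM), which T cells also express, and Lyz2 (16.4 ± 1.37 TPM) were highest, and Fcgr1 and Marco stayed at 0.167 and 0.123 TPM. Of the antigen-presentation genes of MHC class II, the invariant chain Cd74 was at 54.2 ± 14.3 TPM and H2-Ab1 at 17.7 ± 6.79 TPM. The globins Hba-a1 and Hbb-bs reached 25.1 ± 8.19 and 20.2 ± 7.96 TPM.

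List levels were 1.59 ± 0.06 for natural killer and innate-like genes (Tyrobp, 8.26 TPM; Klrb1c, 4.58 TPM), 0.66 ± 0.08 for dendritic cells (Irf8, 8.23 TPM; Itgax, 1.40 TPM) and 0.64 ± 0.12 for neutrophils (S100a8, 2.66 TPM). They were 0.64 ± 0.07 for mast cells and basophils (Kit, 2.43 TPM), 0.65 ± 0.26 for plasma cells, 1.14 ± 0.22 for erythroid cells, 3.59 ± 0.42 for MHC class II, 0.11 ± 0.06 for platelets and 0.07 ± 0.06 for stroma and endothelium, where no gene reached 1 TPM. Of 13 genes of liver, heart, brain, lung, pancreas, skin, kidney and gut, 11 were at 0 in all libraries. Above these levels in the platelet list were Itgb3 at 33.5 ± 1.35 TPM and Itga2b at 4.74 ± 0.995 TPM, while Pf4, a chemokine stored in platelets, was at 0.377 ± 0.468 TPM.

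**Figure D1:**
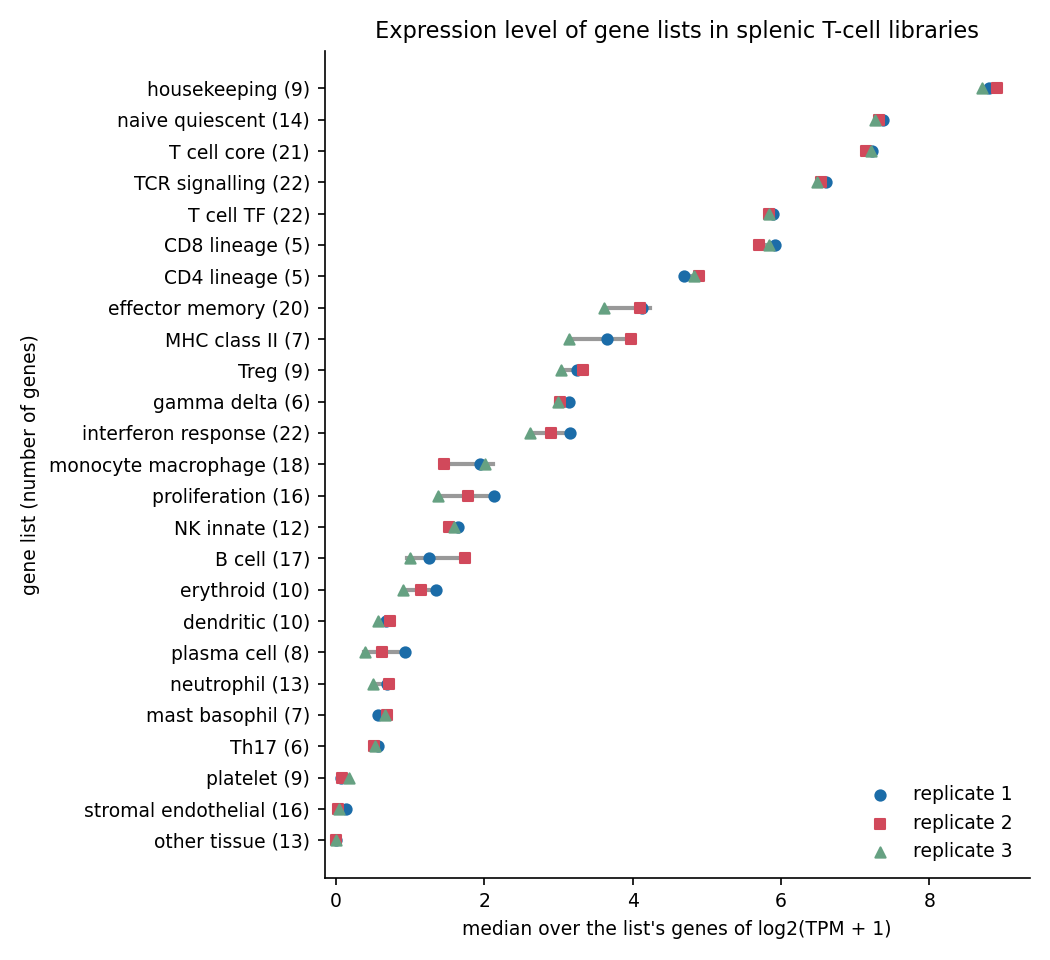
Median of log2(TPM + 1) over the genes of each list (x axis) for 25 lists (y axis, number of genes in brackets). Symbols are the 3 libraries and grey bars the mean ± SD; the T-cell core list sits at 7.19, the B-cell list at 1.33 and the monocyte and macrophage list at 1.81.

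Summed over all transcript entries of each gene, Cd8a had a higher TPM than Cd4. Cd4 (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221), the co-receptor of helper and regulatory T cells, was at 83.0 ± 0.532 TPM. Cd8a (ENSMUSG00000053977.13, chromosome 6, 71373427 to 71379173) and Cd8b1, the chains of the co-receptor of cytotoxic T cells, were at 129 ± 5.89 and 125 ± 4.80 TPM, a Cd8b1 to Cd8a ratio of 0.963 ± 0.0484. The log2 ratio of Cd4 to Cd8a was -0.63 ± 0.07, or 1.55-fold lower for Cd4, and negative in 3 of 3 libraries. Its exact two-sided sign-flip p was 0.25, the smallest possible. Transcript levels per cell of the 2 lineages are not known here, so the ratio is not a ratio of cells. The retained-intron entry Cd8a-203 held 38.8% ± 2.99 of the Cd8a TPM. The protein-coding entries Cd8a-201 and Cd8a-202 were at 50.97 and 28.2 TPM, so the direction against the whole Cd4 TPM rests on counting Cd8a-203. The log2 ratio of Cd4 to Cd8b1 was -0.58 ± 0.06. Entries of Cd4 and Cd8b1 were not split in this way. The CD8 lineage list had a level of 5.82 ± 0.11 with Runx3 at 55.7 ± 4.29 TPM, and the CD4 lineage list 4.80 ± 0.10 with Zbtb7b, the factor that fixes CD4 fate, at 33.9 ± 4.49 TPM.

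Among the lists of helper subsets, that of regulatory T cells had the highest level, followed by that of type 1 helper cells. The lists hold different genes, and the libraries also held Cd8a transcripts, so these levels do not rank the subsets by abundance. Foxp3, the defining factor of regulatory T cells, was at 8.68 ± 0.319 TPM, or 10.5% ± 0.428 of the Cd4 level. Ctla4 (23.5 ± 2.02 TPM), Tnfrsf18 (18.95 ± 3.13 TPM), Ikzf2 (17.8 ± 5.62 TPM) and Il2ra (9.38 ± 1.88 TPM) accompanied it, at a list level of 3.21 ± 0.15. The type 1 list stood at 2.94 ± 0.23 (Stat4, 49.4 TPM; Cxcr3, 12.3 TPM; Tbx21, 6.74 TPM), the follicular list at 1.69 ± 0.16 (Sh2d1a, 18.2 TPM; Bcl6, 4.06 TPM), the type 2 list at 0.75 ± 0.15 (Gata3, 26.8 TPM; Il4, 1.07 TPM) and the type 17 list at 0.54 ± 0.03 (Ccr6, 1.04 TPM). No read was assigned to the cytokine genes Il17a and Il22 in any library, where a count of 0 allows up to 3 counts per library.

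Gamma-delta T-cell genes were a small part of receptor expression. Trdc, the delta constant region (ENSMUSG00000104876.1, chromosome 14, 54142851 to 54148868), was at 8.04 ± 0.856 TPM and made up 1.61% ± 0.18 of the summed Trdc and Trac TPM. The gamma-delta share of TCR constant-region expression was 8.65% on TMM-scaled counts (CPM), which are not divided by the longer Trdc transcript. The gamma constant regions Tcrg-C4, Tcrg-C2 and Tcrg-C1 were at 12.5 ± 2.38, 8.16 ± 1.73 and 6.94 ± 0.135 TPM, and Sox13 and Cd163l1 at 0.540 and 0.453 TPM, for a list level of 3.05 ± 0.08.

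Naive and quiescence genes lay 10.3-fold above effector and memory genes in TPM + 1. The lists hold different genes, so this fold does not measure the share of naive cells. The difference of the list levels, which asks for the resting state of the cells, was 3.37 ± 0.24 (log2), positive in 3 of 3 libraries, with an exact two-sided sign-flip p of 0.25, the smallest possible. All 14 naive and quiescence genes exceeded 10 TPM, with Tcf7, Klf2 and Satb1 highest, followed by Lef1 (239 ± 10.3 TPM), and with Foxo1 lowest (44.1 ± 2.33 TPM). Of 20 effector and memory genes, 12 exceeded 10 TPM. They included Il2rb, a chain of the interleukin 2 and 15 receptors (77.2 ± 8.24 TPM), Nkg7 (55.1 ± 6.31 TPM), the chemokine Ccl5 (43.7 ± 14.5 TPM) and granzyme A, Gzma (31.6 ± 6.51 TPM), while Gzmk and Cx3cr1 lay at 0.543 and 0.273 TPM.

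**Figure D2:**
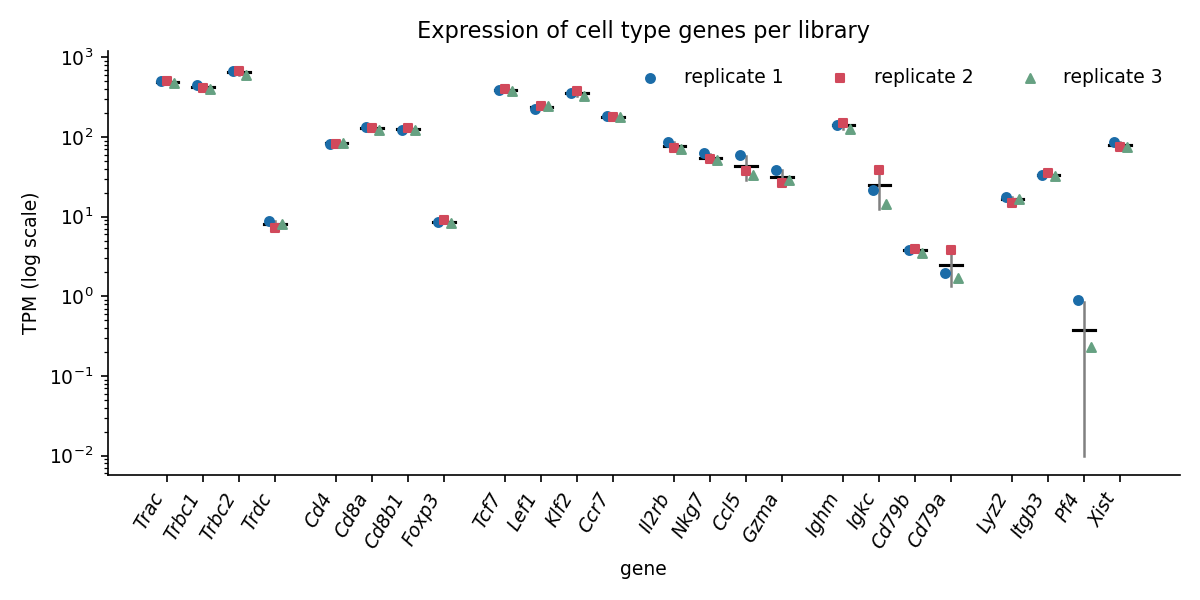
TPM of named cell type genes on a log axis, with 1 symbol per library, a black bar for the mean and a grey line for ± SD (n = 3). Trac stands at 492, Cd4 at 83.0, Cd8a at 129, Ighm at 139.8 and Cd79a at 2.49 TPM; values of 0, such as Pf4 in replicate 2, have no symbol.

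Receptor V segments were read in all T-cell receptor families. V-segment counts per 100 constant-region counts were 43.0 ± 1.19 for the alpha chain, 25.3 ± 1.02 for the beta chain, 28.7 ± 3.01 for gamma and 13.5 ± 0.247 for delta. Reads were assigned to 105 of 108 alpha and to 22 of 22 beta V segments annotated as genes, with those annotated as pseudogenes, such as Trbv24, left out. The posterior SD exceeded 5% of the count for 77 of the alpha and 0 of the beta segments, so single alpha segments, Trav6-5 (10.2%) among them, are uncertain. Trbv29, Trbv13-2 and Trbv2 held the largest shares of the beta V counts, 11.6% ± 0.56, 9.94% ± 0.574 and 8.67% ± 0.485. Trav6-5 and Trav12-2 led the alpha V counts with 3.37% ± 0.287 and 3.20% ± 0.321. Trbc1 made up 39.4% ± 1 of the summed Trbc1 and Trbc2 TPM. Immunoglobulin kappa had 53.0 ± 16.8 V counts per 100 constant counts and the mu heavy chain 1.38 ± 0.375. The V segments named here were chosen after their values were seen.

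The most abundant RNAs were small structured and ribosomal ones. The 20 genes with the highest TPM held 52.9% ± 0.386 of TPM and 30.4% ± 0.375 of estimated counts. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA whose reads were split evenly between them, each held 136915 ± 5056 TPM, and Rn7sk, an RNA that holds back transcription elongation, 60236 ± 1480.3 TPM. Gm26917 and Gm42418, adjacent entries on chromosome 17 (39843013 to 39846341 and 39846958 to 39848788), reached 44491 ± 1194 and 10887 ± 792 TPM, and Gm26917 alone took 12.0% ± 0.204 of counts. Rpph1 and Rmrp, the RNA parts of the RNase P and RNase MRP enzymes, were at 14469 ± 209 and 13853 ± 803 TPM, the snRNA entry Gm24265 at 8475 ± 1313 TPM and Malat1 at 5964 ± 94.9 TPM. The highest protein-coding genes were the elongation factor Eef1a1 (3886 ± 21.1 TPM) and the ribosomal protein gene Rps27 (3772 ± 32.7 TPM).

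Mitochondrially encoded genes took 6.77% ± 0.304 of counts, of which the 2 mitochondrial ribosomal RNAs held 5.88% ± 0.246. Nuclear protein-coding genes held 64.7% ± 0.438 of counts but 34.4% ± 0.871 of TPM, long non-coding biotypes 16.8% ± 0.0697 of counts, ribosomal protein genes 3.71% ± 0.0561, small structured RNAs 7.88% ± 0.188 (3.57% ± 0.28 in the second quantification, and 38.2% ± 0.818 of TPM), replication histones 0.14% ± 0.0182, T-cell receptor segments 0.138% ± 0.00469 and immunoglobulin segments 0.0246% ± 0.00281. The long non-coding share rested largely on Gm26917, with 12.0% ± 0.204 of counts, and Malat1, with 1.94% ± 0.0417. The spike-ins took 0.314% ± 0.00468. At 1 TPM or more in all 3 libraries, 11818 of 55536 genes were detected, among them 9851 of 22028 protein-coding genes, 583 pseudogenes and 545 genes of long non-coding biotypes. The number was 6051 at 10 TPM and 598 at 100 TPM.

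Ptprc, which encodes CD45, carries alternative exons whose use changes with T-cell state. Its transcript with the highest mean share, Ptprc-203, lacks exons 4, 5 and 6 and held 24.7% ± 4.29 of the gene's TPM (23.5% ± 2.62 in the second quantification). Ptprc-213, a 702-nt partial transcript with exon 5 but neither 4 nor 6, held 20.5% ± 0.583 and exceeded Ptprc-203 in replicate 3 (21.1% against 19.9%), the retained-intron entry Ptprc-210 14.3% ± 0.394, Ptprc-204, which lacks exons 4 to 7, 9.74% ± 3.08, and the retained-intron entry Ptprc-201 7.20% ± 0.264, which was 2.55% ± 0.12 in the second quantification. Over the transcripts that include or skip each exon, inclusion was 13.7% ± 1.04 for exon 4 (chromosome 1, 138122456 to 138122584), 41.4% ± 3.21 for exon 5 (138120020 to 138120166), 9.60% ± 1.91 for exon 6 (138117754 to 138117894) and 84.0% ± 5.02 for exon 7 (138116954 to 138117025). The exon 5 value rests on 2 transcripts, and mostly on the partial Ptprc-213. The other, Ptprc-207, which includes exons 4 to 7, held 5.83% ± 1.16 of the gene's TPM. Exon 4 moved to 24.2% ± 1.01 in the second quantification. Of 20 genes with known isoforms, 15 had the same leading transcript in both quantifications, and Ikzf1, Foxp1, Fyn, Satb1 and Runx1, named after their values were seen, did not.

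Some proliferation and histone genes differed between the libraries. Among 13280 genes tested with edgeR for a spread beyond that of genes of like abundance, 75 passed an adjusted p of 0.05, and 755 had an unadjusted p below 0.05. Mki67, a marker of cycling cells, was at 6.27, 4.57 and 2.74 TPM in replicates 1, 2 and 3 (edgeR adjusted p = 0.00171), and Top2a, the topoisomerase of dividing cells, at 11.7, 7.50 and 5.28 TPM (edgeR adjusted p = 0.0119). These were 2 of 16 proliferation genes tested, also 2 adjusted over the list alone. The summed TPM of the list was 179, 178 and 145 in replicates 1, 2 and 3. All 8 replication histones that passed, of 60 tested (24 adjusted over the list alone), were highest in replicate 1 and lowest in replicate 3, such as Hist1h1b at 23.5, 19.9 and 6.85 TPM and Hist1h3b at 43.5, 32.2 and 14.2 TPM. The summed TPM of all 66 histone genes in replicate 1 was 1.47 times that in replicate 3. The deposited posterior SD exceeded 5% of the count for 5 of these 8 histones. Without replicate 3 none of the named genes passed (edgeR adjusted p = 0.203 for Mki67, 0.963 for Top2a, 0.997 for Hist1h1b and 0.867 for Hist1h3b). A non-robust edgeR fit left 28 calls in all, kept Mki67 (adjusted p = 0.015) and ended those of Top2a (0.0645) and all 8 histones (0.0572 to 0.171). Of the histones, 3, 8 and 1 passed without replicates 1, 2 and 3, and 6 of the 7 tested did in the second quantification. Mki67 and Top2a passed without replicate 1, without replicate 2 and in the second quantification.

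The immediate-early and heat-shock genes that passed were lowest in replicate 1. Fos, an immediate-early transcription factor, was at 80.2, 100.8 and 122 TPM (edgeR adjusted p = 0.0027), Fosb at 31.1, 38.6 and 43.7, Egr1 at 17.7, 26.2 and 21.6 and the inducible chaperone Hspa1b at 4.07, 10.5 and 14.5 TPM (edgeR adjusted p = 0.000187). With Hspa1a these were 3 of 23 immediate-early genes (7 adjusted over the list alone) and 2 of 10 heat-shock genes (4 adjusted over the list alone). The immediate-early list as a whole stayed below the 95th percentile of random lists (87.6, or 1.76 in the second quantification). Its mean shift was lowest in replicate 1, but its summed TPM was lowest in replicate 3 (1809, 1956 and 1781 in replicates 1, 2 and 3). Replicate 2 was highest in Cd74 (58.8, 65.7 and 38.3 TPM), 1 of 7 MHC class II genes (5 adjusted over the list alone), in the globin Hba-a2 (11.5, 26.1 and 8.10 TPM), 1 of 6 erythroid genes (4 adjusted over the list alone), and in the immunoglobulin kappa constant region Igkc (21.8, 38.9 and 14.5 TPM), named after its values were seen. Without replicate 1, edgeR adjusted p was 0.245 for Fos, 0.789 for Fosb, 0.818 for Egr1, 0.264 for Hspa1b and 0.485 for Hspa1a. Without replicate 3 it was 0.0557 for Fos, 0.17 for Fosb, 0.342 for Hspa1a, 0.0606 for Hba-a2, 0.0974 for Igkc and 0.927 for Cd74. Without replicate 2 it was 0.996 for Hba-a2, 0.898 for Igkc, 0.0516 for Cd74 and 0.23 for Egr1. The posterior SD of the count was 13.3% for Hba-a2 and 9.79% for Hspa1a, whose reads are shared with copies. The non-robust edgeR fit ended the calls of Fosb, Egr1, Hspa1a, Cd74, Hba-a2 and Igkc (adjusted p of 0.0876 to 0.14). The second quantification ended that of Hba-a2 (edgeR adjusted p = 0.0811).

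Further genes passed outside these groups. The mitochondrial tRNA synthetase gene Lars2 was 2.28-fold higher in replicate 2 than in replicate 1 (edgeR adjusted p = 2.08e-05) and Tspan10, a tetraspanin gene, 16.9-fold higher in replicate 2 than in replicate 3 (edgeR adjusted p = 9.21e-07). The imprinted gene Igf2r was 1 of 10 imprinted genes (2 adjusted over the list alone) and lowest in replicate 2 (15.8, 9.46 and 14.7 TPM). Without replicate 2, edgeR adjusted p was 0.862 for Tspan10 and 0.996 for Igf2r.

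Genes past the threshold also came from classes with near-identical copies. They included 20 snRNA and snoRNA genes, of which 19 were highest in replicate 3 and 19 lowest in replicate 1. These 20 hold 10 distinct sets of counts, since reads of identical copies, such as those of the U1 gene Rnu1a1, were split evenly between them. Of the 20, 6 passed with the non-robust edgeR fit and 6, 19 and 3 without replicates 1, 2 and 3, and 0 could be tested in the second quantification. There were 10 pseudogenes (9 distinct sets of counts), with the lowest edgeR adjusted p for Gm10163 (6.2e-08), whose posterior SD was 205% of its count and whose level was 137 TPM in the first and 6.21 TPM in the second quantification. Of the pseudogenes, 6 passed with the non-robust fit, 5, 7 and 8 without replicates 1, 2 and 3, and 2 of the 5 tested in the second quantification. There were also 3 mitochondrial genes, mt-Co3, mt-Atp6 and mt-Nd4l, of 14 tested (4 adjusted over the list alone). The edgeR adjusted p was 0.998 for mt-Co3 without replicate 3, 0.0923 for mt-Atp6 without replicate 1 and 0.0779 for mt-Nd4l without replicate 2. The second quantification ended the call of mt-Nd4l (0.984) and kept the other 2. For 48 of the 75 genes the deposited posterior SD of the count, a measure of reads that several genes share, exceeded 5% of the count, and their single values are uncertain. Without replicates 1, 2 and 3 in turn, 43, 85 and 35 genes passed. Only 2 genes, Gm10163, with the uncertain counts just given, and Lars2, passed each time. A gene set apart by 1 library alone must fail without it, so such a failure does not show that its difference is absent.

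Mean shifts of whole lists differed between the libraries as well. Of 43 lists, 11 differed between libraries by more than the 95th percentile of 10000 random lists of the same size and mean expression, where chance gives 2.15, and 9 of them did so in the second quantification too. There 13 lists did, the others being small structured RNAs (range 0.76), checkpoint genes, gamma-delta genes and type 1 helper genes. Random lists treat genes as unrelated, so these percentiles describe the libraries and are not p-values. Replicate 1 was highest for replication histones (range 0.68 on the log2 scale, 100th percentile), proliferation (0.63, 99.9), interferon response (0.46, 99.9), effector and memory genes (0.39, 99.4), monocyte and macrophage genes (0.37, 97.6) and homing receptors (0.27, 95.5, against 78.4 in the second quantification). Replicate 2 was highest for MHC class II (0.76, 99.5), B-cell (0.66, 99.9) and erythroid genes (0.56, 99.5). Replicate 3 was lowest for 8 of the 11 lists, namely histones, proliferation, interferon response, effector and memory genes, homing receptors, MHC class II, B-cell and erythroid genes. These values are mean shifts, and list medians did not all follow them. In replicates 1, 2 and 3 the median was 1.95, 1.46 and 2.02 for monocyte and macrophage genes. It was 1.36, 1.14 and 0.91 for erythroid genes. For the other lists just given, the median was highest in the same library as the shift. Heat-shock genes were highest in replicate 3 (0.36, 98.4), though their list median hardly moved (6.11, 6.09 and 6.12 in replicates 1, 2 and 3). Mitochondrially encoded genes were also highest in replicate 3 in mean shift, and lowest in replicate 2 (0.64, 100th percentile, against 6.34 in the second quantification). Their summed share of counts went another way, at 6.42%, 6.98% and 6.92% in replicates 1, 2 and 3, lowest in replicate 1. Of the interferon genes, Ifi27l2a was at 104, 96.7 and 76.3 TPM. No single gene of the B-cell, effector, interferon or monocyte lists passed the edgeR threshold over all genes, with 4 of 16, 3 of 18, 3 of 22 and 0 of 15 passing adjusted over the list alone, 9, 7, 6 and 5 at an unadjusted p below 0.05, and 1, 1, 2 and 0 set apart by DESeq2.

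**Figure D3:**
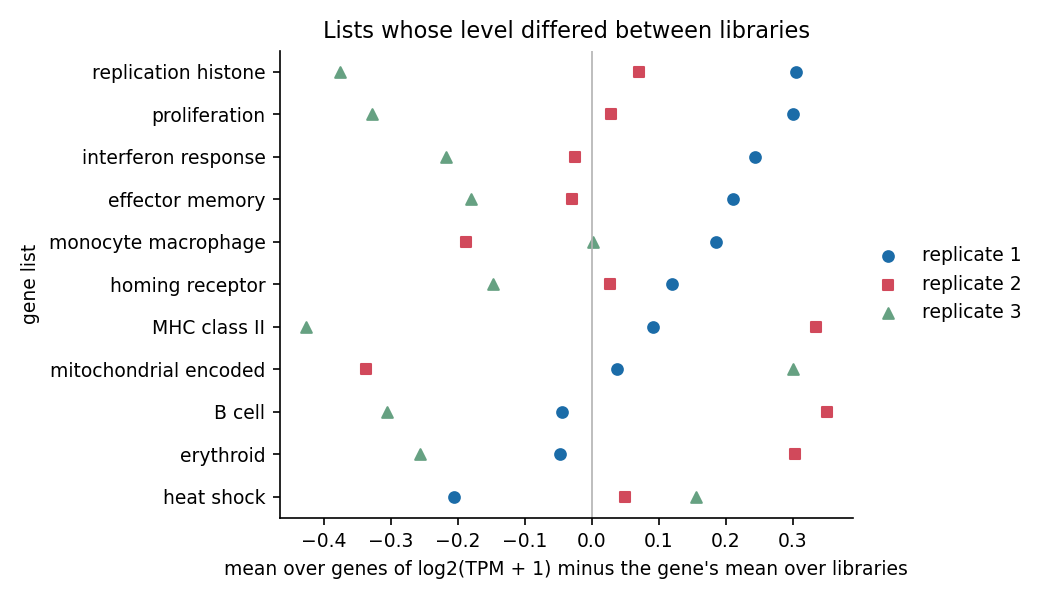
Mean over a list's genes of log2(TPM + 1) minus each gene's mean over the libraries (x axis) for the 11 lists beyond the 95th percentile of random lists (y axis), with 1 symbol per library. Histone and proliferation genes are highest in replicate 1 and B-cell genes in replicate 2.

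General agreement between the libraries was high beside these differences. The median Spearman correlation over 22875 genes was 0.939 ± 0.00155 across the 3 pairs, a correlation across genes, which are not independent replicates. The common biological coefficient of variation, the spread beyond counting error, was 0.0717 for genes and 0.0303 for 33 spike-ins. None of the 21 T-cell core genes passed the edgeR test or was set apart by DESeq2, and 1 had an unadjusted p below 0.05. No pair of libraries agreed within sampling noise (chi-square of 5.25, 4.90 and 4.20 per degree of freedom), so none was a repeat deposit of another. This does not show that they are separate biological samples.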

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

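All tests of explanations below were chosen after the pattern was seen, and all but the test of shared reads for Ighm after the value it measures was seen too. The test of shared reads in variable genes was first written for all 36 such genes that are not nuclear protein-coding (29 of them, 80.6%, had a posterior SD above 5% of the count, against 18.9% of 2279 others). It was split into classes after that value was seen. The bound for Ighm transcripts from T cells was changed after its value was seen. The rule for B or erythroid cells was changed to include the lowest library after its values were seen. Apart from the cell types named below as sources, no biological explanation was tested because there is 1 group.

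The control sequence phiX174, outside the gene measurements, held a mean of 42.3 reads per library, above the bound of 3 counts that an observed 0 allows. The 4 Y-linked genes held a mean of 234 reads per library in the second quantification, although the samples are labelled female. Kdm5d had 178 of these, and Uty and then Ddx3y held most of the rest, and the gene table gave the 4 genes together 1, 3 and 2 counts in replicates 1, 2 and 3. Entries named by a number held a mean of 5.67 estimated counts.

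Ighm stood at 139.8 TPM among B-cell genes of a few TPM. B cells as the source are argued against by the V segments: heavy-chain V counts per Ighm count were at most 3.83% of the kappa V counts per Igkc count in any library. These counts are not divided by transcript length, so part of that gap may come from the lengths of the constant regions. The size of that part was not measured. Lambda chains, with only 15, 4 and 11 V counts in replicates 1, 2 and 3, had 18.99, 5.06 and 26.19 per 100 constant counts. The mu chain had 1.09, 1.80 and 1.25, so the gap to lambda was narrower in replicate 2. Reads shared with near-identical copies are argued against by a posterior SD of 0% of the count. Transcripts that start at the mu constant region in the T cells themselves, without a V segment, remain a candidate explanation. Ighm minus the T-cell core level had an SD of 0.159 (log2) over the libraries, and Ighm minus the level of the other B-cell genes 0.206, and 3 libraries are too few to decide between them.

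Of 6407 transcripts at 10 TPM or more in the alignment-based tables, 355 were at 0 in the second quantification. Transcripts shorter than the mean fragment of 277 nt may be lost there: 89.2% of 204 such transcripts were at 0, against 2.79% of 6203 longer ones, just under the 90% set for this explanation. All 94 under 150 nt and all 57 from there to 200 nt were at 0, but so were 44 of 212 between 300 and 400 nt, and length alone therefore stays open as the whole cause. Absence from the other index is argued against, since 0.563% of the transcripts at 0 lacked an entry.

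The variable genes fall into parts. Reads shared between copies may account for the pseudogene and mitochondrial ones, since 92.3% of 13 (12 genes) had a posterior SD above 5% of the count, against 54.0% of 568 pseudogene and mitochondrial genes that did not pass. For snRNA and snoRNA genes sharing is argued against as the whole cause, as the summed reads of the class differed 1.33-fold between libraries, although 16 of the 20 genes had a posterior SD above 5% of the count, while selection for fragment length cannot be told apart from other causes with 3 libraries (the lowest library, replicate 1, had fragments longer by 18.7 nt than the others, but replicate 3 had more such reads than replicate 2, 9679 against 8852 CPM in sum, with longer fragments, 274 against 267 nt). For the proliferation genes sharing is argued against by a median posterior SD of 0.0309% for Mki67 and Top2a. For the histone genes it is argued against as the whole cause by the 1.47-fold difference of summed histones. The posterior SD exceeded 5% of the count for 5 of the 8 histones that passed. Whether B or erythroid cells carry the proliferation and histone genes stays open. The mean shifts of the B-cell and erythroid lists were up to 0.39 (log2) higher in replicate 2 than in replicate 1. They were lowest in replicate 3, as were those of proliferation and histone genes, and 3 libraries are too few to decide.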

How the results depend on the processing

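The comparisons of list levels, the Cd4 to Cd8a ratio and the counts of detected genes kept their direction and stayed on the same side of their thresholds under every alternative run, except that 6051 genes were detected at 10 TPM by the threshold's construction. Among alternatives to the results of the report, 80 left the value within its bounds, 19 moved it and 0 reversed it. The exact sign-flip p of 0.25 could not pass a threshold under any setting. Alternatives added after seeing the data were the second quantification and the limit of 5% on the posterior SD for variable genes, the second quantification for list shifts, TPM rescaled over nuclear protein-coding genes, and the B-cell list without Ighm. The cause was not tested for any change below unless stated.

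The gamma-delta share of TCR constant-region expression was 8.65% as CPM, which are not divided by transcript length. Variable genes numbered 303 without a filter on low counts, 28 with a non-robust fit, 28 under the limit on posterior SD (fewer genes tested; 27 of 27 calls still tested remained), 125 by DESeq2's marking and 35 to 85 with 1 replicate left out. In the second quantification 103 genes passed, and 34 of the 48 calls tested there remained. The biological coefficient of variation was 0.0826 without the filter, 0.057 under the limit on posterior SD, 0.0687 to 0.0758 with 1 replicate left out and 0.109 as the median over genes in DESeq2, a different estimate. The Spearman correlation was 0.973 at 1 TPM or more and 0.942 in the second quantification. As a share of TPM and of counts in the second quantification, the mitochondrial share was 5.85% and 6.23%, and the spike-in share 0.414% and 0.254%. The second quantification put Ptprc-213 at 21.5%, Ptprc-210 at 12.1% and Ptprc-201 at 2.55%.

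Mean TPM of 211 of 299 named genes moved by more than 1 SD in the second quantification. With a replicate left out, 0 did, but leaving out 1 of 3 libraries cannot move a mean by 1 SD. That 0 was therefore fixed in advance and does not measure stability. Nuclear protein-coding genes held 34.4% of TPM in the first and 46.7% in the second quantification. Over genes at 10 TPM or more in either, the log2 ratio of the second to the first had quartiles of 0.245 and 0.537. A move of a named gene therefore need not be specific to that gene. Of 38 named variable genes, 19 still passed with the non-robust fit and 22, 27 and 17 without replicates 1, 2 and 3. No paired analysis was possible because there is 1 group. Depth limits genes near 1 TPM, where a transcript of 1 kb has 15.41 to 17.03 reads.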

Other observations

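Cytokine, cytokine receptor, homing and metabolic genes were expressed at differing levels. All 19 cytokine receptor genes exceeded 1 TPM, led by the common gamma chain Il2rg at 221 ± 10.9 TPM, Il7r, the receptor for the survival factor interleukin 7, at 124 ± 7.28 TPM and Il27ra at 106 ± 2.92 TPM. Of 15 cytokine genes, 8 exceeded 1 TPM, with lymphotoxin beta, Ltb, at 208 ± 9.02, Il16 at 77.0 ± 1.37 and Tgfb1 at 48.8 ± 2.20 TPM. Homing receptors included Ccr7 (180.5 ± 4.58 TPM) and S1pr1 (139 ± 8.20 TPM), which guide T cells into and out of lymph nodes, and Ccr10 lay at 0.487 ± 0.0404 TPM. Of checkpoint genes, Btla (19.4 ± 0.0404 TPM) and Ctla4 lay highest and Lag3 (2.05 ± 1.29 TPM) and Havcr2 (0.163 ± 0.0666 TPM) lowest, at a list level of 2.35 ± 0.45. Glycolysis genes had a level of 5.24 ± 0.07, with Gapdh at 161 ± 14.1 and the inducible hexokinase Hk2 at 1.12 ± 0.375 TPM. Levels were 5.56 ± 0.07 for cytokine receptors, 1.00 ± 0.22 for cytokines, 3.56 ± 0.35 for homing receptors, 9.65 ± 0.02 for ribosomal protein genes, 8.80 ± 0.10 for housekeeping genes (Actb, 2977 TPM) and 6.92 ± 0.02 for the genes chosen for isoforms.

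Immediate-early genes were expressed at a level of 6.06 ± 0.05, with Junb at 344 ± 36.2, Jund at 248 ± 16.99 and Klf6 at 235 ± 24.5 TPM, and heat-shock genes at 6.11 ± 0.02, with Hspa8 at 682 ± 27.2 TPM. Interferon response genes had a level of 2.90 ± 0.27 and proliferation genes of 1.77 ± 0.38, where Pcna led with 87.0 ± 7.50 TPM and Bub1 was lowest with 0.770 ± 0.502 TPM. Replication histones had a level of 4.58 ± 0.51. Of the nuclear long non-coding RNAs (level 4.55 ± 0.13), Malat1 was followed by Gas5 (239.5 ± 18.3 TPM), Neat1 (133 ± 9.13 TPM) and Snhg1 (117 ± 17.96 TPM). Xist, the RNA of the inactive X chromosome (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), was at 79.2 ± 6.82 TPM, and genes known to escape X inactivation at a level of 5.66 ± 0.06, led by Ddx3x (159 ± 3.44 TPM). Of 17 imprinted genes, 7 exceeded 1 TPM, with Zrsr1 at 31.1 ± 4.33 and Impact at 15.1 ± 1.63 TPM, while H19 was at 0. Of 157 small structured RNA genes 102 were at 0 in all libraries, and of 37 mitochondrially encoded genes 22 were, among them the tRNAs mt-Tw and mt-Ty, so that the level of both lists is 0.

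The quantifications ranked protein-coding genes alike but not all genes. Over 7633 genes at 10 TPM or more in either, Spearman's correlation across genes, which are not independent replicates, was 0.814, and 0.958 over the 6859 nuclear protein-coding ones. The median log2 ratio of the second to the first was 0.38, and 196 genes were at 0 in the second and 42 at 0 in the first. Rmrp (13853 TPM), Gm23444 and Gm23472 (9025 TPM each), Gm24265 and Gm24407 were at 0 in the second. Gm19220, at 0 in the first, had 4449 TPM in the second, Gm47283 298, Gm42860 207, Gm28438 162 and Gm9864 155 TPM. Lars2, a variable gene, had 239 TPM in the first and 698 TPM in the second, and the mitochondrial gene mt-Atp8 1013 TPM and 0.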
